A study of Mus musculus with 12 samples.

How the data were processed

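RNA was measured in the hippocampi of 12 mice in 4 groups of 3: wild-type and knockout mice of a Shank2 line without exons 6 and 7, and wild-type and knockout mice of a Shank2 line without exon 7. Per the labels' protocols, the mice were male knockouts and wild-type littermates, RNA was extracted with TRIZOL, and poly(A) RNA was made into TruSeq libraries with size selection on a gel and read on an Illumina HiSeq. The submitters' processing notes name CASAVA, GSNAP, Cufflinks and the mm10 genome build, with no order or role given. The authors deposited 1 table per mouse with an FPKM value per gene and Ensembl release 74 gene identifiers, per the file headers, and only genes with a value above 0 were listed there. The counting, strand and multiple-mapping settings are not given in the sources used here. Groups were taken from the genotype labels, and each mouse number occurs once in the series, so that replicates are separate animals. No library repeated another: at most 0.00546% of values were equal between any 2 libraries.

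A gene not listed for a mouse was given the value 0. Libraries were scaled by the median of ratios to the geometric mean over the 12511 genes with at least 1 FPKM in all 12 libraries (factors 0.919 to 1.07). Genes with a mean of at least 1 FPKM were tested on the scale log2(scaled FPKM + 1), which understates the fold change of low genes. Symbols of small RNAs, whose FPKM values are unstable because the transcripts are shorter than fragments, were left out (30 genes), which left 14298 genes, 160 of them with no symbol and 260 unlisted in at least 1 library. Symbols, coordinates, transcript lengths and GC content came from GENCODE M21, on the same build as mm10. A symbol was found for 24065 of the 24590 identifiers and a length for 14138 of the genes tested (98.9%). Within a line the correlation of libraries across genes was 0.947 to 0.982 and between lines 0.834 to 0.901, and the first principal component, with 67.0% of the variance, parted the lines. Mitochondrial transcripts made up 6.22 to 7.39% of the summed values in the exon 6-7 line and 10.3 to 14.3% in the exon 7 line. FPKM values keep no read total. Relative depth within a line was estimated from the ratios of low values, between 0.005 and 0.15 FPKM, and whole reads could not be recovered, so that no counting error is attached to any value.

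The test was limma 3.58.1 (limma-trend) in R 4.3.3, with a mean for each of the 4 groups and 1 estimate of spread from all 12 libraries (8 residual degrees of freedom, prior 3.42). Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fitted were knockout minus wild type in each line, the difference of the 2 effects, their mean, and the exon 7 wild type minus the exon 6-7 wild type. For single genes exact permutation tests were added, over 20 relabellings within a line or 400 over both. The correlation of the 2 knockout effects was set against 100 relabellings of genotype within lines (seed 1), and, chosen after the data were seen, against the 72 relabellings that keep in each group 1 of the 4 libraries (set A) that stood apart from the other 8. For 36 gene lists, drawn from textbook knowledge of hippocampal synapses, cell types, neighbouring tissues and cell processes, shifts were tested with camera at a preset correlation of 0.01 and adjusted over the 36 lists of a comparison. Of these lists the choroid plexus, meningeal, blood and neighbouring tissue markers stand for tissue other than hippocampal neurons. Tables and plots were made with Python 3.11.15, jsonlite 2.0.0 and matplotlib 3.10.9.

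The groups, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined, except the alternatives that use the library sets, protein-coding genes alone or the removal of length and GC trends, which were chosen after seeing the data. The rule named, in each line, Shank2, Gabra2 and Nnt; the 10 genes with the largest log2 fold change in each direction among those past the threshold with all 3 knockout mice on one side of all 3 wild-type mice; where fewer than 5 passed, the 5 with the smallest unadjusted p in each direction, as not passing; and up to 4 members with the smallest p of each shifted list and of the GABA-A and NMDA receptor lists. For the other comparisons it named up to 10 passing genes with the smallest p. Clone names were counted and not named, and some genes that the rule selects are not reported here. Outside the rule, Ttr, Wdfy1, Ide, Igf2, Cdkn1c, Mt1, Mt2, Mt3 within the lines, Cd24a in the exon 6-7 line and over both lines, and the sums of the Rps3a copies were chosen after their values were seen.

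Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, FPKM as deposited, quantile normalization, rescaling to TPM, each line fitted alone, array quality weights, robust empirical Bayes, small RNAs kept, camera with an estimated correlation, fry, and each of the 12 mice left out in turn. With a mouse left out, the filter on low values was applied to the mice that remained, a change made after a first look at those results, which otherwise held genes expressed in the missing mouse alone. On simulated data with known changes, the exon 6-7 comparison (14315 genes) recovered 33.3%, 91.0% and 95.5% of genes changed by 0.5, 1 and 2 log2 units, with 5 false calls among 152. The exon 7 comparison (14288 genes) recovered 36.4%, 83.6% and 94.0%, with 10 false calls among 153. Each size was given to 66 or 67 genes at once, with noise independent between genes, so a lone changed gene would be harder to call.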

Results

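Hippocampal RNA was sequenced from 12 mice of 2 lines that carry different deletions in Shank2, the gene of a scaffold protein of the postsynaptic density at excitatory synapses. One line lacks exons 6 and 7 (the exon 6-7 line) and the other lacks exon 7 (the exon 7 line). Each line gave 3 knockout and 3 wild-type mice, all on a mixed C57BL/6J and C57BL/6N background. Each mouse has its own number in the labels, so that p-values of single genes measure the spread between mice and their libraries. The main fit has no term for the library sets described below, so their difference is part of that spread. Camera p-values of gene lists with the preset correlation do not measure that spread alone. They assume a low, fixed correlation of members, whether or not members vary together between mice. With an estimated correlation 0 lists passed in either knockout comparison. The values are FPKM per gene, a measure scaled by transcript length and library size that holds no read counts, so the absolute depth is unknown. Relative depth within a line, estimated from the steps between low values, ran from 0.70 to 1.19. This is a rough estimate, since 33.9% of the ratios behind it, at most, lay within 0.1 log2 units of their mode, and 9.88% for KO990, the mouse at 0.70. In all 24590 genes were listed in any mouse and 16895 in all 12, and the 14298 genes with a mean of at least 1 FPKM were tested. Mice are named below by the genotype and number in the labels. The comparisons asked how each knockout differs from the wild-type mice of its line, whether the 2 deletions act alike, and how the 2 wild types differ.

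In these data 4 libraries, called set A, stood apart from the other 8. Set A was defined by the gene ENSMUSG00000095746, which was not listed in these 4 and was at 218 to 435 FPKM in the other 8. The set A libraries were WT778 and KO776 of the exon 6-7 line and WT628 and KO969 of the exon 7 line. Their mitochondrial shares were 6.72, 7.39, 13.6 and 14.3%, against 6.22 to 6.81% and 10.3 to 10.9% in the other mice of the 2 lines. Each line thus had 1 mouse of each genotype in set A and 2 of each in set B. Modelled as a pair that differs from the other mice of its line, set A moved 67 genes in the exon 6-7 line and 3985 in the exon 7 line, against at most 3 for any other pair, each line being fitted alone. In 1 fit of all 12 libraries the set term passed for 943 and 4424 genes. Because both genotypes are represented equally, changes within set A and within set B are given beside the pooled ones where a gene passed its test.

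Shank2 mRNA was lower in the exon 6-7 knockout and not detectably different in the exon 7 knockout. Shank2 (ENSMUSG00000037541, chromosome 7, 144001928 to 144424494, plus strand, mm10) was at 14.4, 13.8 and 14.9 scaled FPKM in mice WT778, WT809 and WT865 and at 6.22, 7.02 and 6.15 in mice KO776, KO777 and KO864. The means were 14.4 ± 0.576 and 6.46 ± 0.483 (SD, n = 3 each), a log2 fold change of −1.04 (SE 0.119, limma adjusted p = 0.0141), with all 3 knockout mice below all 3 wild-type mice. Within set A the change was −1.09 and within set B −1.02. In the exon 7 line Shank2 was at 36.0, 42.4 and 44.1 in mice WT628, WT993 and WT999 and at 33.2, 43.5 and 44.6 in mice KO969, KO990 and KO994. These means were 40.8 ± 4.24 and 40.4 ± 6.29 (SD, n = 3 each), a log2 fold change of −0.02 with a 95% interval of −0.28 to 0.24 and limma adjusted p = 1. A gene-level value covers the exons that remain, so it checks a genotype label only where the deletion lowers the transcript. It matched the label of each of the 6 exon 6-7 mice and could not check those of the exon 7 mice. The smallest p an exact two-sided permutation test of 3 against 3 can give is 0.1, which Shank2 reached in the exon 6-7 line (exact permutation p = 0.1) and not in the exon 7 line (exact permutation p = 0.9). The exon 6-7 call was lost without WT778 (adjusted p = 0.0730), WT809 (0.0532) or WT865 (0.130) or KO776 (0.123) or KO777 (0.0552), and the adjusted p ran from 5.91e-05 to 0.130 over 27 alternatives.

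**Figure D1:**
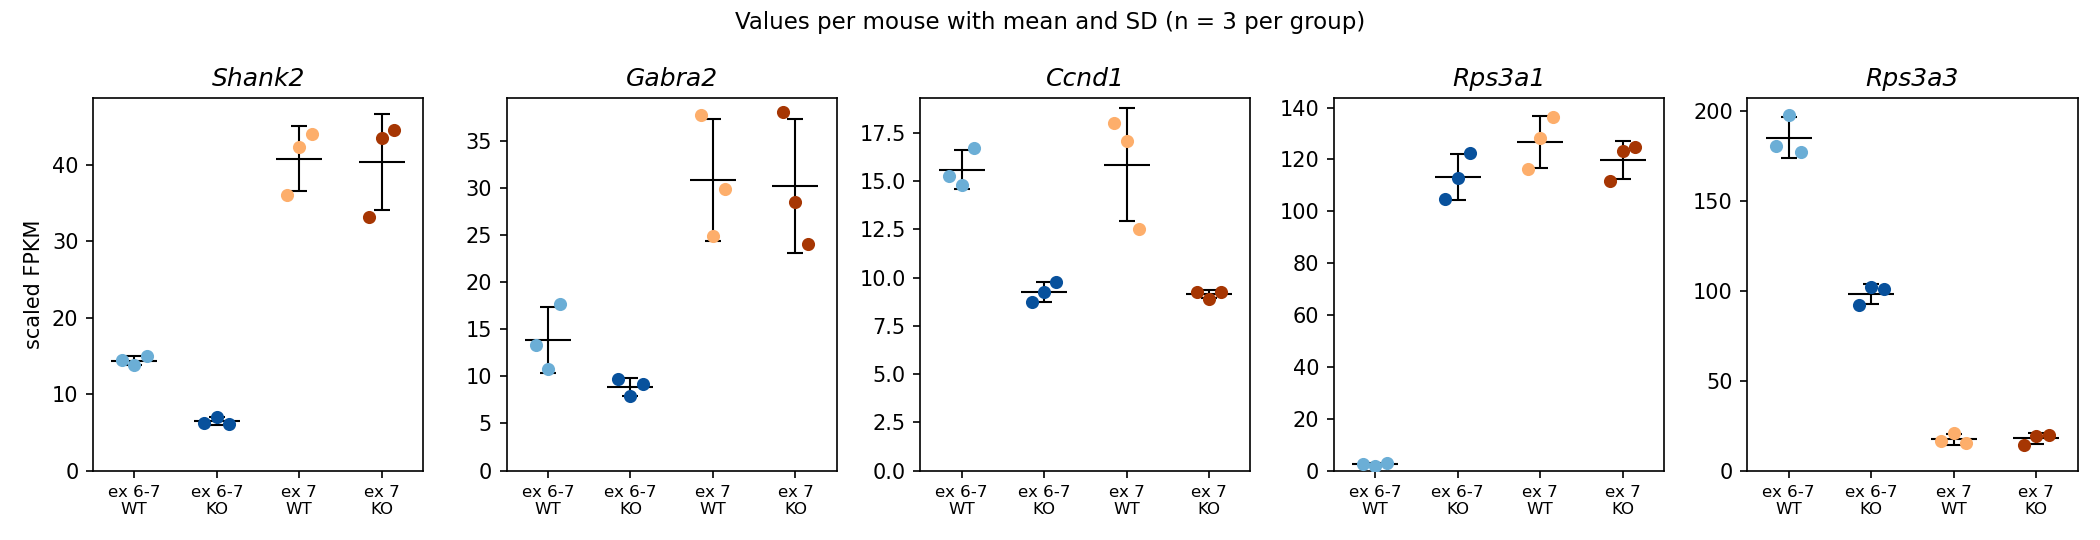
Scaled FPKM of Shank2, Gabra2, Ccnd1, Rps3a1 and Rps3a3 in each of the 12 mice, by group, with the group mean and SD (n = 3). Shank2 lies at 6.15 to 7.02 in the exon 6-7 knockout against 13.8 to 14.9 in its wild type, and Rps3a1 at 113 ± 8.83 against 2.41 ± 0.608.

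In the exon 6-7 knockout 1 other gene passed the test. Rps3a1, the gene of ribosomal protein S3a of the small ribosomal subunit (ENSMUSG00000028081, chromosome 3, 86137940 to 86142702, minus strand), rose from 2.41 ± 0.608 to 113 ± 8.83 scaled FPKM (SD, n = 3 each), a log2 fold change of 5.08 (SE 0.127, limma adjusted p = 1.72e-09), and by 4.85 within set A and 5.20 within set B. Other copies of the gene with shared sequence had lower values. Rps3a3 (chromosome 13, 108670603 to 108671397, plus strand) was at 185 ± 11.2 in wild-type and 98.3 ± 5.59 in knockout mice, a log2 fold change of −0.91 that did not pass (adjusted p = 0.186). It passed with each line fitted alone (adjusted p = 0.0307), with array quality weights (0.0347) and without KO969 (0.0339), in a range of 0.0307 to 0.931 over 26 alternatives. Rps3a2 (chromosome 14) was at 39.4 ± 1.05 and 24.8 ± 3.46 (log2 fold change −0.66, adjusted p = 1). Of the 50-base windows of the Rps3a1 transcript, 61.4% also occur in Rps3a2 and 39.9% in Rps3a3, so the value of each copy is uncertain. The sum of Rps3a1 and Rps3a3 was 188 ± 10.6 in wild-type and 212 ± 13.6 in knockout mice (log2 fold change 0.17, SE 0.0881), and the share of Rps3a1 in it was 1.30 ± 0.386% and 53.5 ± 1.19%. In both groups of the exon 7 line that share was 87.9 ± 2.05% in wild-type and 87.1 ± 1.42% in knockout mice.

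Shank2 and Rps3a1 were the 2 genes past limma adjusted p under 0.05 in this line, and 588 genes had an unadjusted p under 0.05 where 714.9 are expected by chance. Without KO864 the test called 7 genes, and without WT865, KO776 or KO777 it called 1. The next smallest p values belonged to genes that did not pass. Above the wild type lay Bmp6, a secreted bone morphogenetic protein (log2 fold change 0.73, SE 0.132, adjusted p = 0.361), the paraoxonase Pon3 (0.79), the DNA damage kinase Atm (0.79) and the carbonic anhydrase Car12 (0.70). Below it lay Ccnd1, which encodes cyclin D1 of the G1 phase of the cell cycle (−0.69, SE 0.119, adjusted p = 0.326), the leukocyte tetraspanin Cd37 (−0.55, adjusted p = 0.326) and Cst3, the protease inhibitor cystatin C (−0.35).

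Markers of tissues that line the ventricles and cover the brain were higher in the exon 6-7 knockout. As a set, the 20 choroid plexus and ependymal markers rose, with a median log2 fold change of 1.35 and all 20 members above 0 (camera with a preset correlation, adjusted p = 3.11e-19; adjusted p = 0.182 with an estimated correlation; range 5.69e-45 to 0.284 over 28 alternatives). None of them passed over all genes tested, 10 passed when adjusted over the list alone, and in 8 all knockout mice lay above all wild-type mice and in 0 below, where chance separates 10% of genes in either direction. Members that vary together between mice are not separate trials, so the 8 cannot be tested against that 10%. Kl (klotho), the transcription factor Otx2, the bicarbonate transporter Slc4a5 and coagulation factor F5 had log2 fold changes of 1.43, 1.27, 1.38 and 1.20. Much of this lay in 1 mouse. WT865 had Ttr, the transthyretin gene that marks choroid plexus, at 35.6 scaled FPKM, against 3934 to 8494 in the other 5 mice of the line. Without it the median of the list was 0.54 (adjusted p = 3.1e-13). The 14 meningeal and fibroblast markers also rose as a set (median 0.38, 13 above 0, camera adjusted p = 3.71e-10; adjusted p = 0.182 with an estimated correlation; range 5.35e-16 to 0.251). None passed over all genes, 4 passed adjusted over the list alone, and Ogn, Slc13a4, Slc22a6 and Col1a2, a chain of type I collagen, had log2 fold changes of 0.80, 1.15, 0.63 and 0.51.

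Myelin genes were lower. The 20 oligodendrocyte and myelin markers fell as a set (median −0.33, all 20 below 0, camera adjusted p = 1.52e-13; adjusted p = 0.182 with an estimated correlation; range 7.4e-22 to 0.251). None passed over all genes, 5 passed adjusted over the list alone, and 9 had all knockout mice below all wild-type mice and 0 above, against 10% by chance in either direction. As for the choroid plexus list, that count is not a test, since members vary together between mice. The myelin genes Cnp, Mobp and Mog had log2 fold changes of −0.47, −0.37 and −0.39. The median was −0.13 within set A and −0.42 within set B. WT865, the mouse low in choroid plexus genes, had the highest level of this list, a median of 0.36 from the mean of the line. WT809 was at 0.18, WT778 at −0.05, and KO776, KO777 and KO864 at −0.16, −0.21 and −0.15. Of the 19 microglia markers 17 lay below 0 (median −0.13, camera adjusted p = 0.0081; adjusted p = 0.539 with an estimated correlation; range 3.82e-05 to 0.679). Among these were Aif1 (−0.38), the receptor gene Trem2 (−0.42) and its partner Tyrobp (−0.21). The 1 member that passed adjusted over the list alone, Fcrls, went the other way (0.50). The call of the list was lost without WT865 (median −0.06, adjusted p = 0.543), KO776 (adjusted p = 0.328) or KO777 (0.0647), while without WT778 the median was −0.20.

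Genes of protein synthesis and respiration shifted down by small amounts. The 87 nuclear genes of oxidative phosphorylation subunits fell as a set (median −0.12, 81 below 0, camera adjusted p = 1.34e-10; adjusted p = 0.182 with an estimated correlation; range 3.48e-16 to 0.284). Cox6a1 of cytochrome c oxidase was at −0.19 and the complex I genes Ndufa2 and Ndufb9 at −0.27 and −0.16. The 83 nuclear ribosomal protein genes fell as well (median −0.13, 75 below 0, camera adjusted p = 5.35e-08; adjusted p = 0.182 with an estimated correlation; range 5.22e-10 to 0.436). Rps16 was at −0.32. In the first list no member passed by either adjustment. In the second Rps3a1 passed upward over all genes, and adjusted over the list alone it was joined by 1 gene downward. Values in this line followed transcript length (Spearman rho across genes 0.35, genes not being independent replicates), and with the trends of length and GC content removed both medians were −0.07. The ribosomal median was −0.07 without WT809 and −0.08 without KO776, and with quantile normalization the oxidative phosphorylation list was not past its threshold (median −0.04, adjusted p = 0.0569).

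Stress and interferon genes were higher by small amounts as sets in the knockout group of the same line. Of 22 heat shock and endoplasmic reticulum chaperones 16 lay above 0 (median 0.10, camera adjusted p = 0.00236; adjusted p = 0.182 with an estimated correlation; range 1.45e-05 to 0.284). The endoplasmic reticulum chaperone gene Hspa5 was at 0.35, Hspb1 at 0.66, Pdia4 at 0.28 and Hyou1 at 0.15. Of 15 interferon response genes 14 lay above 0 (median 0.15, camera adjusted p = 0.0053; adjusted p = 0.476 with an estimated correlation; range 1.24e-07 to 0.583). Irf9, a transcription factor of the type I interferon response, was at 0.52, Bst2 at 0.37, Rtp4 at 0.30 and Ifitm3 at 0.28. The interferon median was −0.08 within set A and 0.29 within set B. The rises of the chaperone and interferon lists lay partly in different mice. From the mean of the line, the median of KO776 was 0.12 for chaperones and −0.14 for interferon genes. KO864 was at −0.04 and 0.15, and KO777 at 0.05 and 0.24. Of 38 autism-associated genes 30 lay above 0 (median 0.06, camera adjusted p = 0.0014; adjusted p = 0.182 with an estimated correlation; range 2.3e-05 to 0.380). Katnal2, Dyrk1a and Ash1l were at 0.35, 0.21 and 0.17. No member of these 3 lists passed over all genes or adjusted over the list alone. With length and GC trends removed the autism list was at −0.00 (adjusted p = 0.380), and without KO864 at 0.11. The chaperone call was lost without KO776 (adjusted p = 0.0683), and the interferon call without WT778 (0.10), WT865 (0.0593), KO777 (median 0.09, adjusted p = 0.186) or KO864 (0.128).

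Receptor subunits showed no shift as sets in the exon 6-7 line. Gabra2, the alpha 2 subunit of the GABA-A receptor (chromosome 5, 70957597 to 71095849, minus strand), was at 13.9 ± 3.5 in wild-type and 8.91 ± 0.939 in knockout mice (SD, n = 3 each). Its log2 fold change of −0.57 (SE 0.204, 95% interval −1.01 to −0.12) did not pass over all genes (limma adjusted p = 1; exact permutation p = 0.1, the smallest possible). All 3 knockout mice lay below all 3 wild-type mice, and the change was −0.42 within set A and −0.64 within set B. In the exon 7 line Gabra2 was at 30.9 ± 6.50 and 30.2 ± 7.15 (log2 fold change −0.03; exact permutation p = 0.8), and the difference between the lines was −0.53 with a 95% interval of −1.16 to 0.10. The 12 GABA-A receptor subunits had a median of 0.03 and a mean of −0.01 (camera adjusted p = 0.996), with Gabrb2 at 0.33, Gabrd at −0.18 and Gabra3 at 0.06. The 6 NMDA receptor subunits had a median of 0.02 (camera adjusted p = 0.769), with Grin1 at −0.11, Grin2b at 0.15, Grin2c at −0.09 and Grin3a at 0.14. Without WT778 Grin2c was at 0.02, without WT809 Gabra3 at −0.00, and without KO777 Grin2b at −0.00. Nnt, a mitochondrial transhydrogenase gene that carries a deletion in C57BL/6J, was at 0.16 in the exon 6-7 line (−0.01 without KO776) and at −0.11 in the exon 7 line (0.02 without WT628), neither passing.

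In the exon 7 knockout 0 genes passed limma adjusted p under 0.05, and 501 had an unadjusted p under 0.05 where 714.9 are expected by chance. On simulated changes of 1 log2 unit the same test recovered 83.6% of changed genes in this line, and 36.4% of those changed by 0.5. Those simulations changed 66 or 67 genes of each size at once, which eases the adjusted threshold, with noise independent between genes. They do not give the recovery of a few changed genes in these data, which would be lower. The lowest adjusted p was 0.935. Among the genes with the smallest p, above the wild type lay Thbs4, a thrombospondin of the extracellular matrix (log2 fold change 1.25, SE 0.305), Dnph1 (0.64), Pcsk1n, whose product inhibits a prohormone convertase (0.58, SE 0.126), the copper chaperone of superoxide dismutase Ccs (0.57) and the surface glycoprotein gene Cd24a (0.38). Below it lay the ribosomal pseudogene Rpl39-ps (−1.03, SE 0.210), Ccnd1 (−0.72, SE 0.119), Chrna1os, an antisense transcript at an acetylcholine receptor gene (−0.68), Unc13c, a gene of synaptic vesicle priming (−0.47), and the actin regulator gene Phactr1 (−0.37). The values of Rpl39-ps and Chrna1os are uncertain, since the treatment of reads that fit several copies and of strand is not given in the sources used here. The test called 3 genes without WT993, 2 without WT999, and 1 each without WT628, KO969 or KO994.

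Chaperone genes were lower and interferon genes higher as sets in the exon 7 knockout. All 22 heat shock and endoplasmic reticulum chaperones lay below 0 (median −0.14, camera adjusted p = 0.000223; adjusted p = 0.480 with an estimated correlation; range 3.22e-06 to 0.586). Hsp90b1, Hsph1, Pdia6 and Pdia4 were at −0.26, −0.24, −0.22 and −0.18. Of the 15 interferon response genes 14 lay above 0 (median 0.16, camera adjusted p = 0.0011; adjusted p = 0.480 with an estimated correlation; range 7.79e-05 to 0.671). The ubiquitin-like Isg15 was at 0.58, Oasl2 at 0.57, Lgals3bp at 0.43 and Ifitm3 at 0.34, and without KO969 the call was lost (adjusted p = 0.0592). Of the 14 meningeal and fibroblast markers 12 lay above 0 (median 0.17, camera adjusted p = 0.00334; adjusted p = 0.480 with an estimated correlation; range 7.34e-05 to 0.671). Aebp1, Lum, Col1a1 and Islr were at 0.36, 0.36, 0.27 and 0.27. That call was lost without WT628 (adjusted p = 0.139), KO969 (0.113) or KO994 (0.0748), and without WT993 the median was 0.28. No member of the lists that shifted in this line passed over all genes or adjusted over the list alone.

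Neuronal activity genes and ion channels were lower as sets, and blood genes higher. Of 27 activity-regulated immediate early genes 21 lay below 0 (median −0.13, camera adjusted p = 0.0059; adjusted p = 0.682 with an estimated correlation; range 1.02e-09 to 0.800). The transcription factor genes Fos, Egr1 and Fosl2 were at −0.55, −0.28 and −0.28 and the phosphatase Dusp4 at −0.19. The call was lost without WT628 (adjusted p = 0.102), KO969 (median −0.03, adjusted p = 0.276) or KO990 (median −0.03, adjusted p = 0.354), and the median was −0.06 without WT999 and −0.22 without KO994. Of 38 genes on the list of voltage-gated sodium, potassium and calcium channels 31 lay below 0 (median −0.08, camera adjusted p = 0.0148; adjusted p = 0.480 with an estimated correlation; range 0.00479 to 0.671). Kcnn2, whose potassium channel is opened by calcium and not by voltage, Kcnc4 and the auxiliary subunit gene Scn2b were at −0.26, −0.17 and −0.15. This call was lost without WT628 (adjusted p = 0.102), KO969 (0.113) or KO994 (0.0748), and with length and GC trends removed (median −0.03, adjusted p = 0.261). The 6 blood markers had a median of 0.68 (5 above 0, camera adjusted p = 0.00334; adjusted p = 0.480 with an estimated correlation; range 2.26e-05 to 0.671). The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were at 0.73, 0.82, 0.64 and 0.79. Their median was 1.91 within set A and 0.08 within set B, and it was 0.26 without WT628 (adjusted p = 0.397) and 0.42 without KO969 (adjusted p = 0.115). The GABA-A receptor subunits had a median of −0.05 (all 12 below 0, camera adjusted p = 0.110). The list passed without WT993 (median −0.15, adjusted p = 0.0291), WT999 (−0.14, adjusted p = 0.0438) or KO969 (−0.17, adjusted p = 0.0209), in a range of 0.0209 to 0.801, and its median ran from −0.17 to 0.05 over 25 alternatives. Gabra3, Gabrb1, Gabrb2 and Gabrd were at −0.22, −0.21, −0.17 and −0.09. The NMDA receptor subunits had a median of −0.04 (camera adjusted p = 0.865), with Grin1, Grin2a, Grin2c and Grin3a at 0.07, −0.11, −0.14 and 0.05. Without WT628 Gabrd was at 0.05, Gabrb2 at 0.00 and Grin1 at −0.03, and without KO994 Grin1 was at −0.00.

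**Figure D2:**
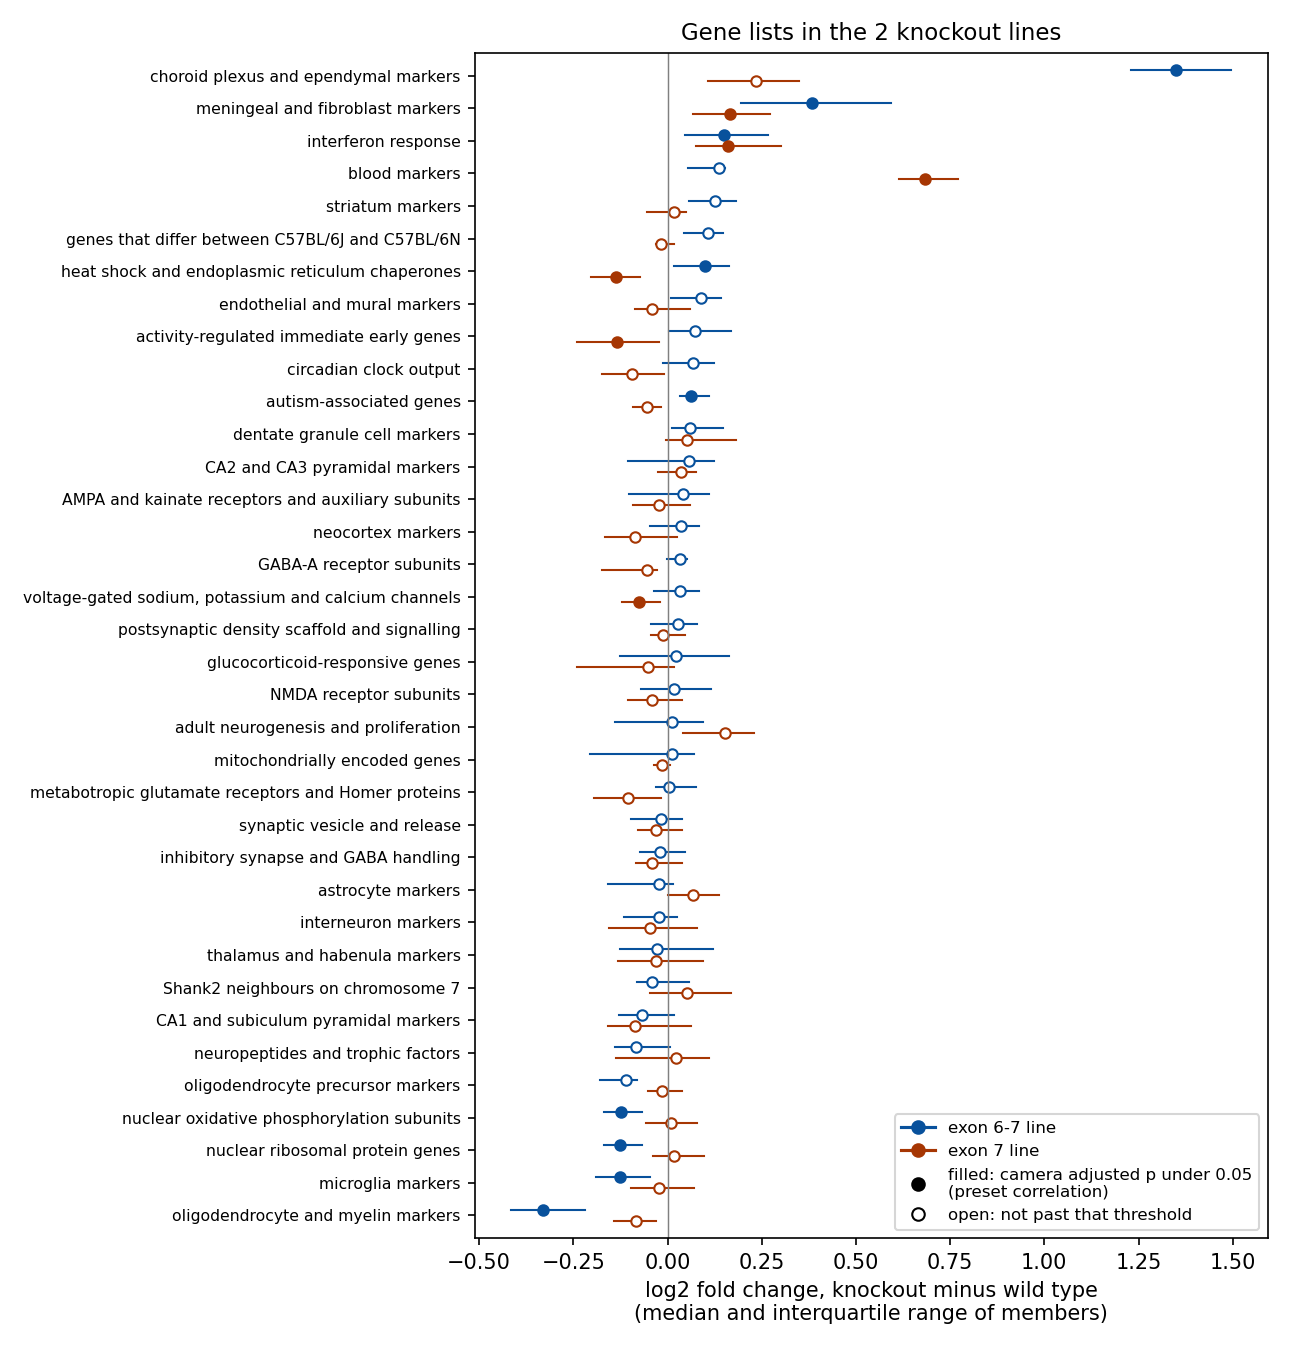
Median log2 fold change, knockout minus wild type, of each of 36 gene lists in the exon 6-7 line and the exon 7 line, with the interquartile range of the members. Filled points are lists past camera adjusted p under 0.05 with the preset correlation, 9 in the exon 6-7 line and 6 in the exon 7 line, and with an estimated correlation 0 lists were past it in either line.

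**Figure D3:**
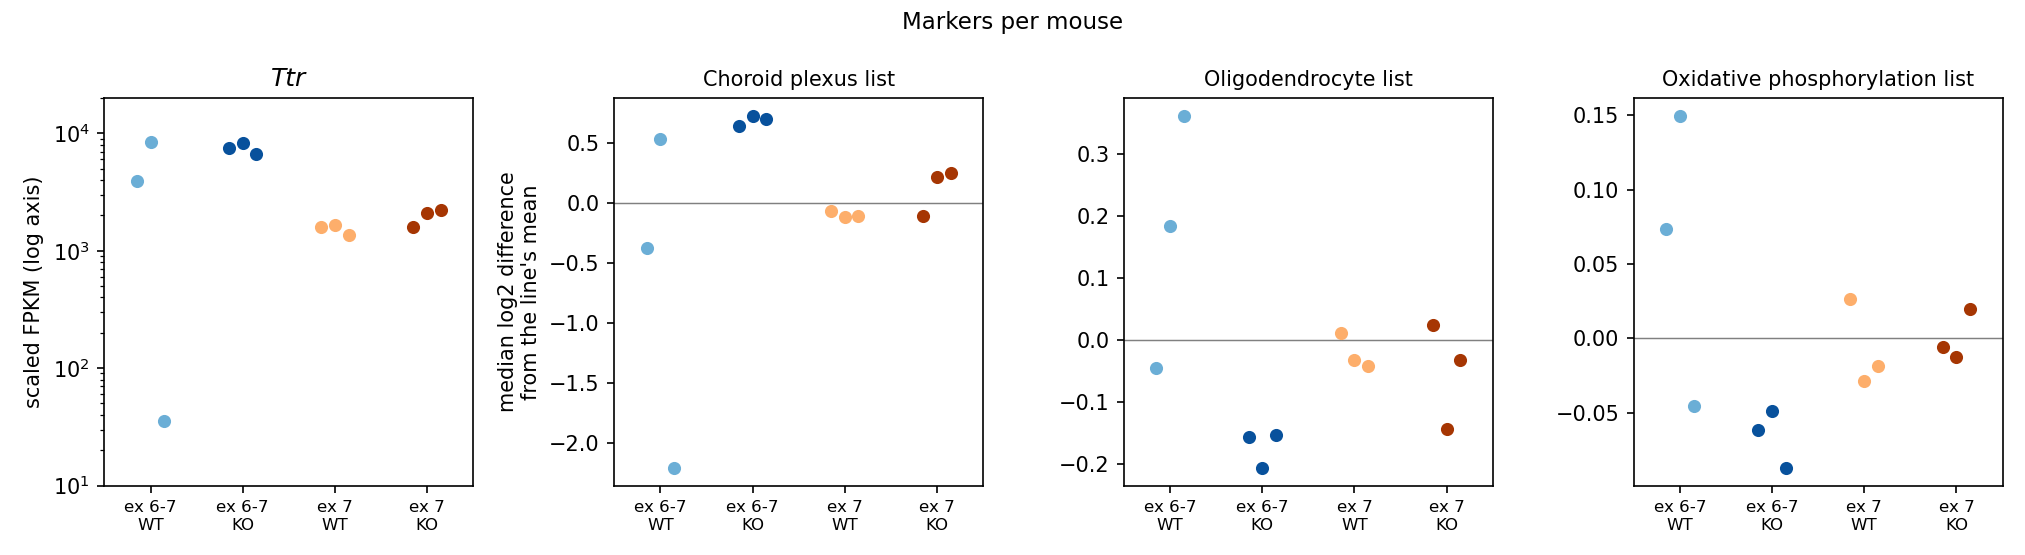
Scaled FPKM of Ttr on a log axis, and the median log2 difference from the mean of the line of the choroid plexus, oligodendrocyte and oxidative phosphorylation lists, for each of the 12 mice. WT865 of the exon 6-7 line has Ttr at 35.6 against 3934 to 8494 in the other mice of that line.

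The remaining lists were not past the threshold in either line with all 12 mice, given here as median log2 fold change in the exon 6-7 and exon 7 lines. Among synaptic genes, the inhibitory synapse and GABA handling list was at −0.02 and −0.04, AMPA and kainate receptors and auxiliary subunits at 0.04 and −0.02, metabotropic glutamate receptors and Homer proteins at 0.00 and −0.11, postsynaptic density scaffold and signalling genes at 0.03 and −0.01, and synaptic vesicle and release genes at −0.02 and −0.03. Among neuronal types, interneuron markers were at −0.02 and −0.05, dentate granule cell markers at 0.06 and 0.05, CA1 and subiculum pyramidal markers at −0.07 and −0.09, CA2 and CA3 pyramidal markers at 0.06 and 0.03, adult neurogenesis and proliferation genes at 0.01 and 0.15, and neuropeptides and trophic factors at −0.08 and 0.02. Astrocyte markers were at −0.02 and 0.07, oligodendrocyte precursor markers at −0.11 and −0.01, and endothelial and mural markers at 0.09 and −0.04. Markers of neighbouring tissue were at 0.04 and −0.09 for neocortex, −0.03 and −0.03 for thalamus and habenula, and 0.13 and 0.02 for striatum. Circadian clock output was at 0.07 and −0.09, glucocorticoid-responsive genes at 0.02 and −0.05, mitochondrially encoded genes at 0.01 and −0.02, Shank2 neighbours on chromosome 7 at −0.04 and 0.05, and genes that differ between C57BL/6J and C57BL/6N at 0.11 and −0.02. For lists past the threshold in the exon 6-7 line alone, medians in the exon 7 line were 0.23 for choroid plexus and ependymal, −0.08 for oligodendrocyte and myelin and −0.02 for microglia markers, 0.01 for oxidative phosphorylation subunits, 0.02 for ribosomal protein genes and −0.05 for autism-associated genes. For those past it in the exon 7 line alone, medians in the exon 6-7 line were 0.14 for blood markers, 0.07 for immediate early genes and 0.03 for voltage-gated channels. With library set as a term 10 and 8 lists passed in the 2 lines, in place of 9 and 6. Those added were oligodendrocyte precursor markers in the exon 6-7 line (camera adjusted p = 0.0140, range 0.00742 to 0.297, past the threshold in 13 of 25 alternatives) and in the exon 7 line oligodendrocyte and myelin markers (0.0180, range 0.0180 to 0.691) and autism-associated genes (0.0266, range 0.0266 to 0.661). Other calls were gained with 1 mouse left out, given with the median and the adjusted p. For the exon 6-7 line, immediate early genes passed without WT778 (0.15, adjusted p = 0.00344), KO777 (0.13, adjusted p = 0.00189), KO864 (0.10, adjusted p = 0.0232), KO969 (0.07, adjusted p = 0.0400) or KO994 (0.08, adjusted p = 0.0149) and with length and GC trends removed (0.12, adjusted p = 0.00842), in a range of 0.00189 to 0.959. Without WT809 endothelial and mural markers (0.14, adjusted p = 0.000245, range 0.000245 to 0.549), CA1 and subiculum markers (−0.11, adjusted p = 0.0147, range 0.0147 to 0.860), striatum markers (0.07, adjusted p = 0.0258, range 0.0258 to 0.372) and oligodendrocyte precursor markers (−0.17, adjusted p = 0.00742) passed. Oligodendrocyte precursor markers also passed without KO776 (−0.16, adjusted p = 0.0176), KO969 (adjusted p = 0.0423) or KO994 (0.0492), and striatum markers without KO994 (adjusted p = 0.0445). Astrocyte markers passed without WT778 (−0.06, adjusted p = 0.0275, range 0.0197 to 0.855), circadian genes without KO864 (0.13, adjusted p = 0.0462, range 0.0462 to 0.655) and postsynaptic density genes without WT865 (0.05, adjusted p = 0.0351, range 0.00938 to 0.656), while blood markers were at −0.22 in set B alone (adjusted p = 0.0347, range 0.0347 to 0.959). For the exon 7 line, the lists past without WT999 were dentate granule cell (0.18, adjusted p = 0.00152, range 0.00152 to 0.492), CA1 and subiculum (−0.10, adjusted p = 0.0441, range 0.0441 to 0.443), astrocyte (0.06, adjusted p = 0.0441, range 0.0195 to 0.366) and oligodendrocyte and myelin markers (−0.11, adjusted p = 0.0495) and the metabotropic receptors and Homer proteins (−0.15, adjusted p = 0.0441, range 0.0441 to 0.550). Choroid plexus and ependymal markers passed without WT809 (adjusted p = 0.0113), WT865 (0.000597) or KO969 (median 0.35, adjusted p = 0.0444), in a range of 0.000597 to 0.282 and in 7 of 25 alternatives. Glucocorticoid-responsive genes passed without WT628 (−0.23, adjusted p = 0.0440, range 0.0440 to 0.941), thalamus and habenula markers without KO994 (−0.12, adjusted p = 0.0455, range 0.0455 to 0.801), and circadian genes without KO864 (adjusted p = 0.0475) or KO990 (−0.08, adjusted p = 0.0224), in a range of 0.0224 to 0.477. Autism-associated genes passed without KO777 (adjusted p = 0.0438) or KO864 (0.0475), and dentate markers without KO864 (0.0495) and with length and GC trends removed (0.08, adjusted p = 0.00927). Median, mean and test differed in sign in the exon 6-7 line for the GABA-A receptor subunits, the mitochondrially encoded genes (median 0.01, mean −0.09), the glucocorticoid-responsive genes (median 0.02, test down), the neurogenesis genes (median 0.01, mean −0.0033), the thalamus and habenula markers (median −0.03, mean 0.00091) and the Shank2 neighbours (median −0.04, mean 0.0025). In the exon 7 line they differed for the substrain list (median −0.02, mean 0.05), the Shank2 neighbours (median 0.05, test down), the neuropeptides (median 0.02, mean −0.03), the interneuron markers (median −0.05, mean 0.01), the mitochondrially encoded genes (median −0.02, mean 0.01) and the striatum markers (median 0.02, mean −0.01).

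The test of the difference between the 2 knockout effects called 1 gene, Rps3a1, whose change was 5.16 log2 units higher in the exon 6-7 line (limma adjusted p = 7.26e-08), and 570 genes had an unadjusted p under 0.05 where 714.9 are expected by chance. For Shank2 the difference was −1.02 with a 95% interval of −1.39 to −0.66, which did not pass over all genes (adjusted p = 0.466). It did pass with library set as a term (adjusted p = 0.00721), with array quality weights (0.0237), with length and GC trends removed (0.00222) and without KO969 (0.0354), and the adjusted p ran from 0.00222 to 1 over 26 alternatives. The test called 4 genes without KO864, 3 without WT993, KO969 or KO994, and 2 without WT778 or WT628. Between the lines 11 lists differed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.205, and without KO969 6 differed. Chaperones differed by a median of 0.24, with 21 of 22 members more positive in the exon 6-7 line (camera adjusted p = 1.02e-06; adjusted p = 0.205 with an estimated correlation), and by 0.36 without KO990. Autism-associated genes differed by 0.13, with 37 of 38 members more positive in that line (adjusted p = 0.302 with an estimated correlation), and by 0.02 with length and GC trends removed (adjusted p = 0.300, in a range of 8.56e-06 to 0.300). Choroid plexus and ependymal markers differed by 1.18 (adjusted p = 0.560 with an estimated correlation), and by 0.36 without WT865 and 1.80 without WT809. Oligodendrocyte and myelin markers differed by −0.26 (adjusted p = 0.402 with an estimated correlation), and by −0.12 without WT865. The difference between the lines did not pass for microglia markers (camera adjusted p = 0.310) or blood markers (0.117). With 1 mouse left out it passed for microglia markers without WT778 (median −0.15, adjusted p = 0.0288) or KO864 (−0.19, adjusted p = 0.0262), in a range of 0.0262 to 0.974, and for blood markers without WT778 (−0.89, adjusted p = 0.00503) or WT993 (−0.86, adjusted p = 0.00226), in a range of 0.00226 to 0.840. Metabotropic receptors and Homer proteins passed without WT865 (0.13, camera adjusted p = 0.0378), KO777 (0.14, 0.0487) or WT999 (0.16, 0.0497). Without WT809 endothelial and mural (0.12, 0.00527) and oligodendrocyte precursor markers (−0.11, 0.0474) passed. Neuropeptides passed without WT999 (−0.13, 0.0418), and postsynaptic density genes without WT628 (0.08, 0.0134).

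Over both lines together Ccnd1 fell and Rps3a1 rose. Ccnd1 (ENSMUSG00000070348, chromosome 7, 144929931 to 144939925, minus strand) was at 15.6 ± 1.01 and 9.26 ± 0.523 scaled FPKM in wild-type and knockout mice of the exon 6-7 line and at 15.9 ± 2.95 and 9.15 ± 0.204 in those of the exon 7 line (SD, n = 3 each). Its mean log2 fold change was −0.70 (SE 0.0842, limma adjusted p = 0.0235). All 6 knockout mice lay below all wild-type mice of their line, and the exact permutation p over relabellings within lines was 0.005, the smallest that 400 relabellings can give. This is no separate support, since Ccnd1 was picked from all genes for its small p. Cd24a, which did not pass over all genes, had the same exact permutation p of 0.005. The changes within set A and set B were −0.74 and −0.67 in the exon 6-7 line and −0.89 and −0.63 in the exon 7 line, and the difference between the lines was 0.02. Ccnd1 lies on the same chromosome as Shank2. The adjusted p ran from 0.000797 to 0.263 over 26 alternatives and was past the threshold in 16. It was not past it without WT778 (adjusted p = 0.0670), WT809 (0.0554), WT865 (0.119) or WT993 (0.0542) or without KO776 (0.125), KO777 (0.127), KO969 (0.0840), KO990 (0.124) or KO994 (0.0528), with log2 fold changes of −0.78 to −0.66 when any 1 mouse was left out. Within a line Ccnd1 passed in 1 of 27 alternatives, without WT999 (adjusted p = 0.0256 in the exon 6-7 line and 0.0243 in the exon 7 line, in ranges of 0.0256 to 1 and 0.0243 to 1). The call over both lines came from 6 knockout against 6 wild-type mice. The change of Rps3a1 over both lines, 2.50 (adjusted p = 1.04e-07), came from the exon 6-7 line alone, with −0.08 in the other. The mean change of Shank2, −0.53, did not pass (adjusted p = 0.218), but did with library set as a term (0.00509), with array quality weights (0.0204) and with length and GC trends removed (0.00257), in a range of 0.00257 to 0.777 over 26 alternatives. In all 510 genes had an unadjusted p under 0.05, and the test called 6 genes without KO864 and 1 gene without WT865 or KO776, KO777, KO969 or KO990.

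Over both lines 10 lists shifted with the preset correlation and 0 with an estimated one (lowest adjusted p = 0.219), and the preset correlation gave 7 without WT778 or WT865, 6 without WT628 or WT993 and 8 with library set as a term. A mean over both lines can come from a single line. Choroid plexus, myelin, microglia, oxidative phosphorylation and ribosomal lists passed in the exon 6-7 line alone, and blood markers in the exon 7 line alone. Except for microglia and blood markers, these shifts also differed between the lines with the preset correlation. All 15 interferon response genes lay above 0 (median 0.20, camera adjusted p = 1.07e-06; adjusted p = 0.306 with an estimated correlation), as did 13 of 14 meningeal and fibroblast markers (median 0.27, adjusted p = 0.219 with an estimated correlation), of which 5 passed adjusted over the list alone. So did all 20 choroid plexus and ependymal markers (median 0.80, adjusted p = 0.330 with an estimated correlation). Oligodendrocyte and myelin markers were at −0.20 (19 of 20 below 0; adjusted p = 0.219 with an estimated correlation). These 4 lists passed in all 25 alternatives run with the preset correlation, although the choroid plexus median was 0.36 without WT865 and the interferon median 0.11 without KO777. The other 6 did not. Blood markers (0.41) lost the call with library set as a term (adjusted p = 0.0623) and without WT778 (median 0.27, adjusted p = 0.225), WT628 (0.20, adjusted p = 0.341) or KO969 (adjusted p = 0.102), in a range of 3.75e-05 to 0.510, and were at −0.06 in set B alone. CA1 and subiculum pyramidal markers (−0.07) lost it with library set as a term (adjusted p = 0.0695) and without WT778 (median −0.03, adjusted p = 0.366), WT865 (0.102), KO777 (0.113), KO864 (0.134), WT628 (0.173), WT993 (median −0.04, adjusted p = 0.124), KO990 (0.0950) or KO994 (0.102), in a range of 0.00640 to 0.366. Dentate granule cell markers (0.08) lost it without WT809 (adjusted p = 0.112), WT865 (0.110), KO864 (0.0561), WT628 (median 0.0086, adjusted p = 0.227), WT993 (0.165) or KO990 (0.131), in a range of 0.000488 to 0.227, and were at 0.13 without WT999. Microglia markers (−0.08) lost it without WT865 (median −0.02, adjusted p = 0.378), KO776 (0.206), WT628 (0.0741) or WT993 (0.106), in a range of 0.000139 to 0.378, and were at −0.13 without KO864. Oxidative phosphorylation subunits (−0.06) lost it without WT809 (adjusted p = 0.0514) and with quantile normalization (median −0.0019, adjusted p = 0.815), in a range of 5.33e-10 to 0.815. Ribosomal protein genes (−0.04) lost it without WT778 (adjusted p = 0.0681), WT809 (median −0.02, adjusted p = 0.192), KO776 (median −0.02, adjusted p = 0.242), WT993 (0.0822) or KO969 (0.0798), in a range of 0.000120 to 0.815, and were at 0.0071 when rescaled to TPM. Calls were gained with 1 mouse left out for immediate early genes without KO994 (median −0.11, camera adjusted p = 0.0141) and endothelial and mural markers without WT809 (0.05, 0.0132). GABA-A receptor subunits gained it without KO969 (−0.08, camera adjusted p = 0.0200).

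Across 14298 genes the log2 fold changes of the 2 lines showed no detectable correlation. Pearson's r was −0.024, within the central 95% of 100 relabellings of genotype within lines (−0.194 to 0.224; permutation p = 0.703). Spearman's rho was −0.077 (permutation p = 0.515), and 45.6% of genes had the same sign in both lines. Genes are not independent replicates, which is why the relabellings set the expected range. They can also part the library sets unevenly between genotypes, and over the 72 relabellings that keep the sets balanced it was −0.119 to 0.119 (permutation p = 0.722, and 0.403 for rho). The 2 effects share no library. Pearson's r was −0.113 within set A and 0.033 within set B, and it was above 0 without WT778 (0.0021), KO776 (0.027), WT628 (0.0056) or KO994 (0.0090).

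The wild-type mice of the 2 lines differed in most genes, far more than knockouts differed from wild types. Of 14298 genes 9505 passed (limma adjusted p under 0.05), 4814 higher and 4691 lower in the exon 7 line, and 3305 differed by more than 1 log2 unit. The autism-associated genes had a median of 1.43 with 37 of 38 higher in the exon 7 line, 36 of them past the threshold over all genes (camera adjusted p = 2.9e-12; adjusted p = 0.033 with an estimated correlation). The ribosomal protein genes had a median of −1.16 with 82 of 83 lower, 79 of them past it (camera adjusted p = 1.59e-19; adjusted p = 0.033 with an estimated correlation). These were the 2 of 11 shifted lists that held with an estimated correlation, and 13 shifted with library set as a term. The wild-type lists were not tested with the trends of length and GC content, described below, removed. Their shifts therefore cannot be told apart from those trends. Oxidative phosphorylation subunits were at −1.24 (adjusted p = 0.0563 with an estimated correlation) and voltage-gated channels at 1.17 (0.0908). Of the 10 genes with the smallest p, all with adjusted p of 2.57e-08 or less, 9 were higher in the exon 7 line. They were Rps3a1 (log2 difference 5.24), Stxbp5l (3.47), the calcium channel gene Cacna1e (3.43), the postsynaptic density gene Lrrc7 (2.80), the lysosomal trafficking gene Lyst (2.51), Kctd16, an auxiliary subunit of GABA-B receptors (2.49), Sgip1 (2.33), Dock4 (2.19) and the motor protein gene Myo5a (1.74). The metallothionein gene Mt3 was lower (−1.99). The value of Rps3a1 is uncertain, since it shares sequence with other copies. The sum of Rps3a1 and Rps3a3 was lower in the exon 7 wild type (log2 difference −0.38, SE 0.0881). The mean share of Rps3a1 in that sum was 87.9% there and 1.30% in the other wild type. The difference of 5.24 therefore cannot be told apart from a shift of reads between the copies. The line cannot be told apart from any batch that follows it, since each line holds its own libraries.

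This difference followed transcript length. Spearman's rho across 14138 genes was 0.661 with length and −0.407 with GC content, and the median log2 difference was −0.81, −0.36, 0.00, 0.32 and 0.90 over 5 equal groups of genes from the shortest to the longest transcripts. With both trends removed 6811 genes passed, of which 5360 were shared with the 9505. The median of all genes was −0.13 for FPKM as deposited and 0.13 after rescaling to TPM, and the calls then split into 4061 higher and 5549 lower, and 5557 higher and 3886 lower.

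**Figure D4:**
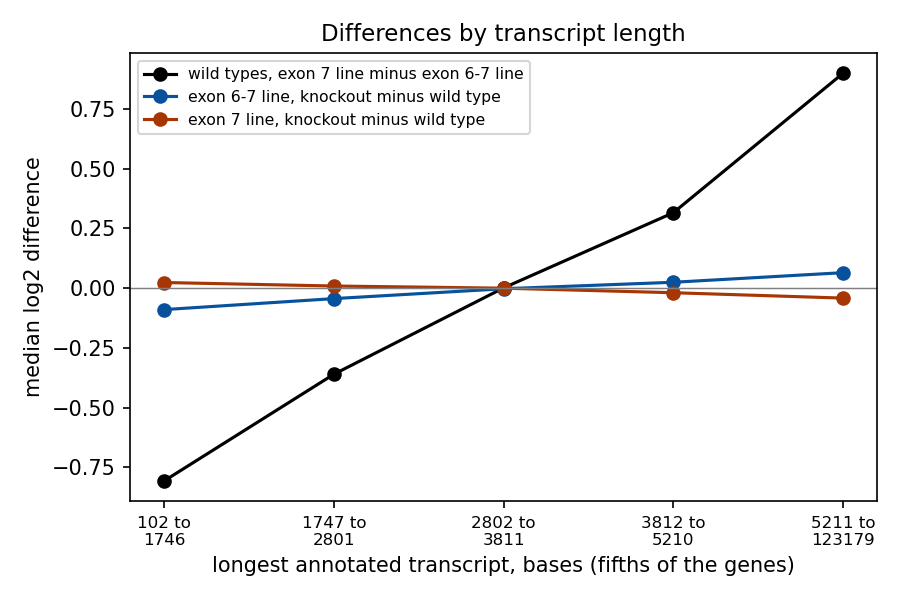
Median log2 difference in 5 equal groups of genes by transcript length (102 to 1746, 1747 to 2801, 2802 to 3811, 3812 to 5210 and 5211 to 123179 bases), for the wild types (exon 7 line minus exon 6-7 line) and for knockout minus wild type in each line. The wild-type difference runs from −0.81 to 0.90, the exon 6-7 knockout from −0.09 to 0.06 and the exon 7 knockout from 0.02 to −0.04.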

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

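The tests of single patterns below were chosen after the results were seen, apart from the test on Nnt and the counts over other splits of the mice, which were set before, except for the splits that keep the library sets balanced.

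Rps3a1 stood out because its response differed between the lines, by 5.16 log2 units. Each set holds both genotypes of each line equally, so a shift common to a set cancels from this change and from those of the genes below. The library sets do not account for the change, and the smaller of its values within set A and within set B was 4.85. That value was in set A, where single mice are compared. Reads shared between copies may account for it: the summed value of Rps3a1, Rps3a2 and Rps3a3 differed between genotypes of the exon 6-7 line by 0.057 on the log2 scale, while Rps3a3 had a log2 fold change of −0.91. A candidate explanation is that a sequence variant in one of the copies, which lie on other chromosomes than Shank2, moved reads from one copy to another, and this was not tested, since no reads were used here. A change in transcription of Rps3a1 with an equal and opposite change of its copies stays open.

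Ccnd1 was lower in all 6 knockout mice of 2 lines whose knockout effects showed no detectable correlation across genes. The library sets do not account for it, since the weakest of its 4 changes within a set and line was −0.63. For 13 listed cell types or tissues, the furthest that a lower quartile of members reached in both lines was −0.14, for oligodendrocyte and myelin markers, against −0.69 for Ccnd1. A loss of cells is not excluded by this, since the values do not show which cells express Ccnd1. A loss of a subtype, or of different types in each line, would also be missed. A variant or regulatory element linked to the targeted region of chromosome 7 cannot be told apart from an effect of the loss of Shank2, because every knockout mouse carries that region: 0 of 14 other neighbours passed over both lines adjusted over the list alone (log2 fold changes −0.18 to 0.42), and no knockout mouse reached the lowest wild-type mouse of its line. Both may be the cause, and the call held with library set as a term and was lost when any 1 of 9 mice was left out and in set B alone, where 4 fewer mice gave a log2 fold change of −0.65 against −0.70 (adjusted p = 0.263, in a range of 0.000797 to 0.263).

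Gabra2, which did not pass over all genes, was lower in the exon 6-7 knockout by both library sets, the weaker change being −0.42, and by −0.63 with length and GC trends removed, so neither accounts for it. Alleles of C57BL/6J and C57BL/6N that still segregate may account for it, since the mice are of mixed background. The SD of Nnt over 12 mice lay at percentile 19.2 of genes of like level (80.6 within the exon 6-7 line and 58.5 within the exon 7 line), a value set in advance to speak against segregation, but that bound was wrong for Gabra2: Nnt lies on chromosome 13 and Gabra2 on chromosome 5, so one can be fixed while the other segregates. Of the other genes that differ between the substrains, Wdfy1 lay at percentile 98.9 within the exon 6-7 line, under the bound of 99 set after the data were seen, and at 47.6 within the exon 7 line, Ide lay at 33.0 and 95.3, and Gabra2 itself cannot be typed from FPKM. Segregating alleles and an effect of the knockout therefore cannot be told apart here.

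The change of Shank2 differed between the lines by −1.02 log2 units, which was past an unadjusted p under 0.05 and not the adjusted one (adjusted p = 0.466). It passed with library set as a term (adjusted p = 0.00721), array quality weights (0.0237), length and GC trends removed (0.00222) and without KO969 (0.0354), in a range of 0.00222 to 1 over 26 alternatives. With the preset correlation the shifts of 11 lists differed between the lines, by median log2 differences (exon 6-7 effect minus exon 7 effect) of 1.18 for choroid plexus and ependymal markers, 0.24 for heat shock and endoplasmic reticulum chaperones, 0.23 for meningeal and fibroblast markers, 0.20 for activity-regulated immediate early genes, 0.17 for circadian clock output, 0.13 for autism-associated genes and 0.11 for voltage-gated channels. The other 4 were −0.13 for oxidative phosphorylation subunits, −0.14 for ribosomal protein genes, −0.17 for astrocyte markers and −0.26 for oligodendrocyte and myelin markers. Without WT865, where choroid plexus genes were low, the choroid plexus list was at 0.36 and the oligodendrocyte list at −0.12, and without WT809 the choroid plexus list was at 1.80, while chaperones were at 0.36 without KO990. Meningeal markers lost the call with library set as a term (adjusted p = 0.102) and without WT778 (median 0.14, adjusted p = 0.195), WT865 (0.12, adjusted p = 0.169), KO777 (0.08, adjusted p = 0.217), WT993 (0.12, adjusted p = 0.389), KO969 (adjusted p = 0.0666) or KO990 (0.191), in a range of 6.6e-05 to 0.401, and were at 0.36 without WT809. Immediate early genes lost it without KO776 (median 0.12, adjusted p = 0.0806) or KO969 (0.12, adjusted p = 0.0501), in a range of 1.77e-09 to 0.186, and were at 0.34 without KO994. Circadian genes lost it without WT865 (median 0.11, adjusted p = 0.132), KO776 (0.10, adjusted p = 0.0965), KO777 (adjusted p = 0.0595), WT993 (0.0662), WT999 (0.0689) or KO969 (0.212), in a range of 0.00238 to 0.212. Astrocyte markers lost it without WT865 (adjusted p = 0.296), KO777 (0.0573), WT993 (0.125) or KO969 (0.0724), in a range of 0.00339 to 0.296. Voltage-gated channels lost it without WT809 (median 0.06, adjusted p = 0.273), KO776 (adjusted p = 0.237), WT999 (0.0512) or KO969 (median 0.07, adjusted p = 0.0902), in a range of 0.00222 to 0.919. With length and GC trends removed the autism-associated genes (median 0.02, adjusted p = 0.300, in a range of 8.56e-06 to 0.300) and the ribosomal protein genes (median −0.07, adjusted p = 0.0584, in a range of 7.25e-08 to 0.0584) lost it. In set B alone the meningeal, immediate early, circadian and channel lists lost it. None of the 11 held with an estimated correlation, where the lowest adjusted p was 0.205. Groups of 3 mice were not tested for single mice that lie far from the others.

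Other splits of the mice were counted for each result of the fits. Within a line 3 mice against 3 make 10 splits, too few for a share under 0.05. As many genes as the real count of 2 in the exon 6-7 line came from 3 of 10 splits (highest other 3), and as many lists as the real 9 from 3 of 10 (highest other 10). For the exon 7 line the real 0 genes were reached by 10 of 10 splits (highest other 1) and the real 6 lists by 3 of 10 (highest other 7). For the wild types 1 of 10 splits, the real one, reached 9505 genes, and the highest other gave 1. Over 100 relabellings within lines, 41 gave as many genes as the 1 whose response differed between the lines (highest other 5), 11 as many as the 2 changed across both lines (highest other 3), and 16 as many as the 11 lists that differed (highest other 15), so chance is not excluded by this test for these 3 counts. Such relabellings can part the library sets unevenly between genotypes, so that their counts include the differences between the sets. Of all 72 relabellings that keep the sets balanced, 37 gave as many genes as the 1 that differed (highest other 3), 14 as many as the 11 lists (highest other 15) and 2 as many as the 2 genes changed across both lines (highest other 3), a share under 0.05 for the last of these in a test chosen after the data were seen.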

How the results depend on the processing

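The alternatives that use library sets, protein-coding genes alone or the removal of length and GC trends were chosen after the results were seen, and the others were set before. Over 29 alternatives, 12 of them with 1 mouse left out, 2870 of 2903 values of 109 gene results stayed on their side of the threshold with their direction, 10 were lost, all of them Ccnd1 over both lines, 12 gained (Shank2 between and over the lines, Rps3a3, and Ccnd1 within a line) and 11 reversed. These leave out Shank2 and Gabra2 within each line, which are given below, Shank2 in the exon 6-7 line passing in 20 of 27 alternatives. Most of the 109 results are genes named as not passing, for which staying on their side was all but given. The total therefore does not measure how firm the knockout calls are. Ccnd1 over both lines passed in 16 of 26 alternatives. Of 420 values of 15 list results within the lines 356 stayed, 63 were lost and 1 reversed. Rps3a1 passed in every setting run for the exon 6-7 line, for the difference between the lines and for both lines together. Of the changes below, those with mice left out or set B alone have fewer mice, and otherwise the cause was not tested.

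Camera with estimated correlation called 0 lists in the exon 6-7 line and 0 in the exon 7 line, and fry 0 and 0. In the exon 7 line array quality weights gave 3 lists, set B libraries alone 2 and protein-coding genes alone 11. In the exon 6-7 line 1 gene changed with a pseudocount of 5 and 1 when rescaled to TPM, 5 with no filter on low values, 4 with each line fitted alone and 4 with set B libraries alone. Of the exon 7 line 1 gene changed with a pseudocount of 0.1, 1 with no filter and 4 with set B alone. The response differed between the lines for 2 genes with a pseudocount of 0.1, 2 with array quality weights, 2 with small RNA genes kept, 3 with library set as a term, 8 with set B alone and 2 with length and GC trend removed. Across both lines 4 genes changed with no filter, 6 with set B alone and 3 with library set as a term. Lists that differed between the lines were 7 with set B alone, and lists shifted over both lines 6 when rescaled to TPM.

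Shank2 in the exon 6-7 line lost its call with a pseudocount of 5 (−0.76, adjusted p = 0.0614) and when rescaled to TPM (−1.04, adjusted p = 0.0525), in a range of 5.91e-05 to 0.130. In the exon 7 line, where it did not pass, it changed sign when rescaled to TPM (0.027), with array quality weights (0.013), with set B alone (0.024) and with length and GC trend removed (0.0078). Gabra2 in the exon 7 line changed sign when rescaled to TPM (0.012) and with length and GC trend removed (0.0074), and Gabrd there with array quality weights (0.047) and set B alone (0.12). The correlation of the knockout effects was 0.0336 with set B alone and 0.0225 with protein-coding genes alone. The autism-associated list of the exon 6-7 line was at −0.00075 with length and GC trend removed.

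With 1 mouse left out, genes changed in the exon 6-7 line ran from 1 (without WT865, KO776 or KO777) to 7 (without KO864), in the exon 7 line from 0 to 3 (without WT993), for the difference between the lines from 1 to 4 (without KO864) and across both lines from 1 (without WT865, KO776, KO777, KO969 or KO990) to 6 (without KO864). Lists shifted in the exon 7 line ran from 3 (without WT628 or KO969) to 12 (without WT999), and the correlation from −0.0635 to 0.0273. Shank2 ran from −1.10 to −1.01 in the exon 6-7 line and from −0.11 to 0.11 in the exon 7 line, and Gabra2 in the exon 7 line from −0.21 to 0.12. Nnt ran from −0.0064 to 0.27 and from −0.21 to 0.021 in these lines, Gabra3, Grin2b and Grin2c in the exon 6-7 line from −0.0019 to 0.15, −0.00013 to 0.36 and −0.16 to 0.016, and Gabrd, Gabrb2 and Grin1 in the exon 7 line from −0.16 to 0.049, −0.29 to 0.0013 and −0.028 to 0.18.

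No paired analysis was possible because no mouse number occurs in more than 1 group. The labels call the wild types littermates but do not tie any mouse to another, so litters could not be used either. Library set was used as a term, as given above. Count models were not run, since whole reads could not be recovered from FPKM. The difference between the lines, their mean and the wild types cannot be fitted in a line alone, and the choice of empirical Bayes or of lines fitted alone has no bearing on the correlation. Depth is unknown, so the precision of low values is too.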

Other observations

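The metallothioneins, which bind zinc and copper, were singled out after their values were seen. In the exon 6-7 line Mt1, Mt2 and Mt3 had log2 fold changes of −0.38, −0.60 and −0.33, and in the exon 7 line 0.30, 0.44 and 0.16, none of them passing over all genes. Mt2 was at 732 ± 106 scaled FPKM in wild-type and 482 ± 51.7 in knockout mice of the exon 6-7 line, and at 119 ± 12.3 and 163 ± 22 in those of the exon 7 line (SD, n = 3 each). The difference between the lines for Mt2, −1.04, did not pass over all genes (limma adjusted p = 0.831), and with library set as a term Mt2 was among the 3 genes called for that difference. All 3 metallothioneins were lower in the exon 7 wild type than in the exon 6-7 wild type, by log2 differences of −1.72 for Mt1, −2.60 for Mt2 and −1.99 for Mt3.

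Cd24a, a surface glycoprotein gene of immature neurons among other cells, was singled out over both lines after its values were seen. It was at 12.7 ± 0.255 and 16.3 ± 1.14 scaled FPKM in wild-type and knockout mice of the exon 6-7 line and at 15.4 ± 1.35 and 20.3 ± 0.648 in those of the exon 7 line (SD, n = 3 each), with all knockout mice above all wild-type mice of their line. The mean log2 fold change of 0.36 did not pass over all genes (limma adjusted p = 0.267). Among the Shank2 neighbours on chromosome 7 the imprinted genes Igf2 and Cdkn1c had mean log2 fold changes of 0.41 and 0.42, which did not pass adjusted over the list alone (adjusted p = 0.289 for each).

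Wdfy1 in the exon 6-7 line was at 7.37, 6.75 and 3.81 scaled FPKM in WT778, WT809 and WT865 and at 11.7, 9.71 and 3.31 in KO776, KO777 and KO864.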
